A study of Homo sapiens with 15 samples.

How the data were processed

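RNA sequencing measured gene expression in 15 libraries of K562 cells, in 5 groups of 3, all taken after 1 h of treatment. Per the labels' protocols, cells received Cas9FCPF by transfection, alone or together with sgRNA, and then either compound at 1 µM. Trizol was used to isolate RNA, and Azenta carried out quality control and sequencing. The authors deposited 1 table of raw read counts per library, with 57500 genes in each, in the column layout of a feature counting program per the file headers. The aligner, the genome build, the annotation release, the library kit and the use of strand in counting are not given in the sources used here. Of the gene identifiers, 56898 were found in GENCODE release 29 and 96.3% of these had the same start and end there, so coordinates are given in that build, GRCh38. Gene symbols came from a table of Ensembl identifiers, which named 41395 of the identifiers. Counts from near-identical copies, such as the replication-dependent histone genes, and from overlapping or antisense genes may be shared between genes, and values for the histone genes are uncertain for this reason.

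Groups were taken from the labels. The control libraries are labelled as untreated wild type, whereas the text of the series names DMSO as the control, and nothing states that the control cells were transfected. Every comparison of a treated group with the control therefore includes transfection, Cas9FCPF and compound together. The labels do not name the target of the sgRNA.

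The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filterByExpr, which left 15517 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 15 libraries, so that the 5 groups shared 1 estimate of the spread, and the biological coefficient of variation was 11.1%. Of 9 comparisons, 8 were between pairs of groups and 1 was the difference between the sgRNA effects under the 2 compounds (the interaction). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are given with their standard error (SE) or 95% interval. Levels are library-scaled counts (CPM) computed here from the deposited counts, as mean ± SD of 3 libraries, and log2 CPM values carry a prior count of 2. Library totals of 12625669 to 17544518 counts set the counting error, which is small beside the spread between libraries except for genes at a few CPM.

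The model, its covariates, the gene lists and the rule for naming genes were set before the data were examined. Named genes are MYC, its neighbours on chromosome 8 and 10 markers of the response to BET inhibitors, then per comparison up to 12 protein-coding genes with the largest change in each direction (mean CPM of at least 5, adjusted p under 0.05, and no overlap between the libraries of the groups), and up to 4 members of each list with the smallest p. The 26 lists hold 684 genes: MYC target genes, the MYC dimerisation network, the MYC neighbourhood, BET response markers, BET proteins and P-TEFb, Mediator and chromatin cofactors, histones, erythroid genes, myeloid and megakaryocytic genes, immediate early genes, interferon, NF-kB, p53, heat shock, ATF4 and unfolded protein, NRF2, cholesterol and glycolysis genes, G2/M genes, S phase and E2F genes, ribosomal proteins, mitochondrially encoded genes, and markers of B cells, T and NK cells, epithelial cells and fibroblasts. The files held no entry for 6 of these genes under the names used, among them the histone gene H3C2, which is named HIST1H3B here. Lists were tested with camera (limma 3.58.1) against all other genes with a preset correlation of 0.01, adjusted over 216 tests, of which 84 passed. With a correlation estimated from the residuals 5 passed, and both adjusted p-values are given in the text.

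The test was run on simulated data for the comparison of JQ1 without sgRNA with the control, over 15238 genes. It recovered 50% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 86.4% of those changed 4-fold, and 5.2% of its calls were false. For JQ1-FCPF with against without sgRNA, simulated data with no change gave 0 calls. Simulated counts were drawn independently for each gene, without deviations shared across a library, so these rates do not cover such deviations in the real libraries. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom between 3 and 48.9. Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, a fit of only the groups compared, the title letter as a block, and leaving out each library. A correction for GC content and length, known for 99.5% of the tested genes, and leaving out 2 libraries together were added after the data were seen.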

Results

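Gene expression was measured in K562 cells, a human line derived from chronic myeloid leukaemia. JQ1 is a small molecule that blocks the bromodomains of the BET proteins, which read acetylated histones. JQ1-FCPF is the form of the compound named for the FCPF peptide tag on Cas9FCPF, the Cas9 protein transfected into the cells. The title of the series speaks of dCas9, which does not cut DNA, whereas the labels speak of Cas9. The 5 groups of 3 libraries were the control, JQ1 without sgRNA, JQ1 with sgRNA, JQ1-FCPF without sgRNA and JQ1-FCPF with sgRNA, each compound at 1 µM for 1 h. Totals were 12625669 to 17544518 counts per library, with 22970 to 27248 genes detected. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

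The first principal component, with 29% of the variance, held the control libraries between -24.7 and -20.9 and the 6 JQ1 libraries between 16.8 and 24.6. All 3 libraries of JQ1-FCPF without sgRNA lay at the control end, between -21.8 and -18.4. Of the JQ1-FCPF libraries with sgRNA, replicates 1 and 3 lay at -16.7 and -14.8, whereas replicate 2 lay at 32.2. All 3 shared low values on the second component, between -40 and -16.4. Mitochondrially encoded genes took between 2.31% and 7.46% of counts, the highest share being in JQ1 with sgRNA replicate 1.

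**Figure D1:**
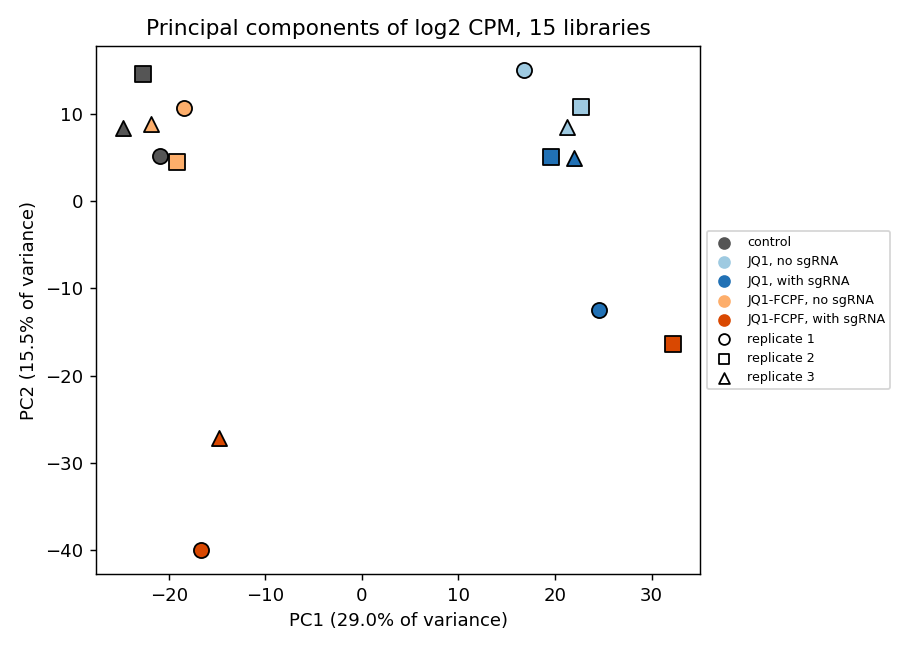
Principal components 1 and 2 of log2 CPM in the 15 libraries, coloured by group and shaped by replicate, with the percent of variance on each axis. JQ1-FCPF with sgRNA replicate 2 lies at 32.2 on the first component, apart from the other libraries of its group at -16.7 and -14.8.

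MYC, a transcription factor gene, was taken from background knowledge of the study as the target of its sgRNA, which the labels do not name, and was measured at chromosome 8, positions 127735434 to 127741434 (the whole gene, ENSG00000136997). It stood at 197 ± 8.74 CPM in the control, 153 ± 9.54 with JQ1 without sgRNA, 128 ± 26.8 with JQ1 and sgRNA, 168 ± 30.7 with JQ1-FCPF without sgRNA and 59.5 ± 1.95 with JQ1-FCPF and sgRNA (SD, n = 3). Under JQ1-FCPF, MYC was 2.83-fold lower with sgRNA than without (log2 fold change -1.50 ± 0.14 SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.67e-07). The 3 libraries of JQ1-FCPF with sgRNA, at log2 CPM of 5.84 to 5.93, lay below all 12 others, the lowest of which was 6.69. Under JQ1 the sgRNA gave a log2 fold change of -0.27 with a 95% interval of -0.54 to 0.01, which did not pass the test (edgeR adjusted p = 0.603). The 2 sgRNA effects differed by -1.24 ± 0.19 on the log2 scale (edgeR adjusted p = 0.00187).

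Against the control, MYC fell by 1.73 on the log2 scale with JQ1-FCPF and sgRNA (3.31-fold, edgeR adjusted p = 4.37e-08) and by 1.54-fold with JQ1 and sgRNA (edgeR adjusted p = 0.00486). For JQ1 without sgRNA the log2 fold change of MYC was -0.36 (95% interval -0.63 to -0.09, edgeR adjusted p = 0.0739). It passed when only those 2 groups were fitted, with no filter on low counts, and without JQ1-FCPF with sgRNA replicate 2 and JQ1 with sgRNA replicate 1, the 2 libraries that stand apart, and over 13 alternatives its adjusted p ranged from 0.000441 to 0.225. For JQ1-FCPF without sgRNA it was -0.22 (95% interval -0.50 to 0.05, edgeR adjusted p = 1). Among the 9 tested neighbours of MYC on chromosome 8, TRIB1 was the 1 gene that changed under JQ1-FCPF with sgRNA, 1.73-fold lower than without sgRNA (edgeR adjusted p = 0.00722), and 1 of 9 also passed adjusted over the list alone. PVT1, next to MYC, had a log2 fold change of -0.01 there (95% interval -0.28 to 0.27).

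**Figure D2:**
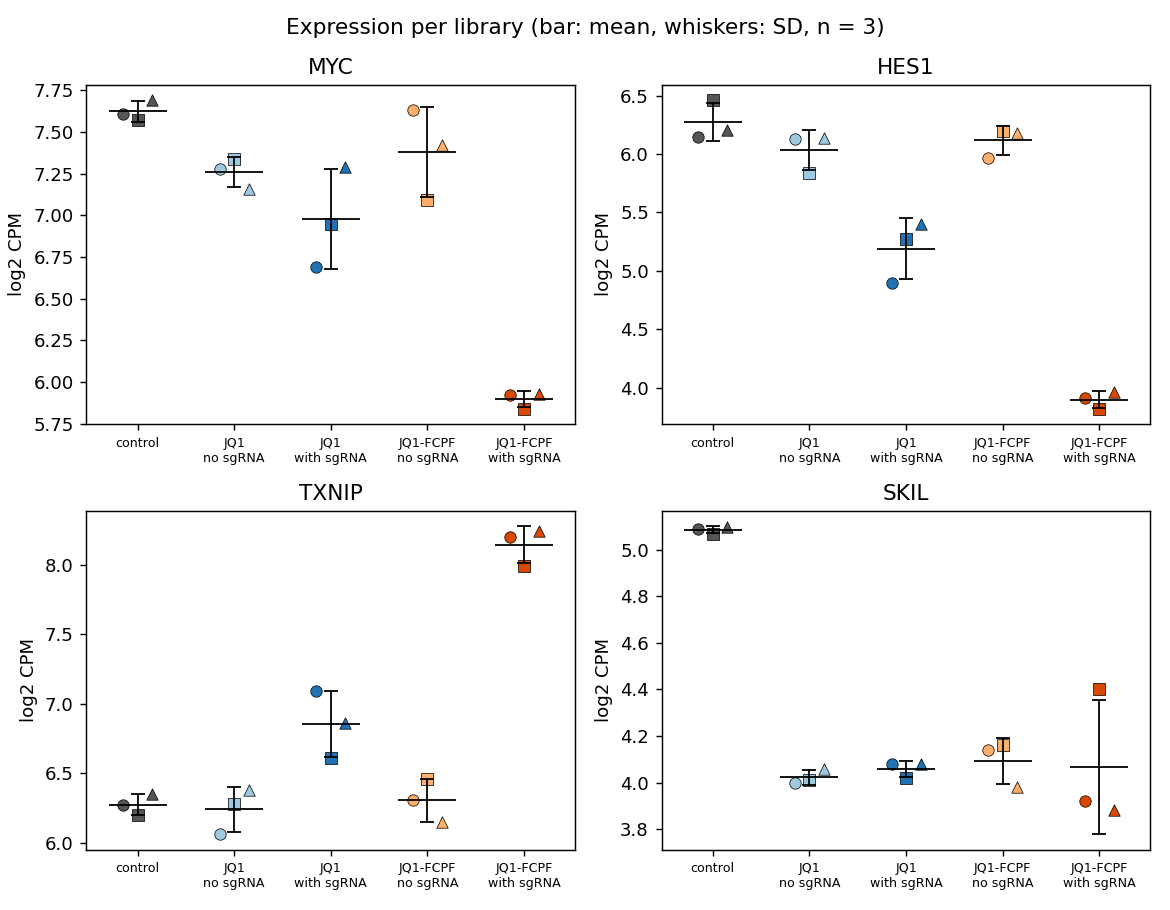
Log2 CPM of MYC, HES1, TXNIP and SKIL in each of the 15 libraries, by group, with marker shapes for replicates, lines for group means and whiskers for SD (n = 3). MYC lies between 5.84 and 5.93 with JQ1-FCPF and sgRNA and at 6.69 or above elsewhere, and SKIL lies between 5.07 and 5.10 in the control and at 4.40 or below elsewhere.

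The effect of the sgRNA on the conjugate was read from JQ1-FCPF with against without sgRNA. Genes with large falls besides MYC were HES1, a repressor in the Notch pathway, from 69.2 ± 5.98 to 14.8 ± 0.743 CPM (4.67-fold, edgeR adjusted p = 1.38e-09), and FOXA2, a forkhead transcription factor, 5.49-fold (edgeR adjusted p = 3.12e-07). CYP26A1, which degrades retinoic acid, fell 3.75-fold, LPAR5, a receptor for lysophosphatidic acid, 3.29-fold, RHOH 2.98-fold, CITED2, a partner of CBP and p300, 2.95-fold, C10orf71 2.87-fold, INKA1 2.83-fold and BHLHE40, a repressor linked to the circadian clock, 2.77-fold. TXNIP, which binds thioredoxin and limits glucose uptake, rose from 79.4 ± 8.41 to 284 ± 25.9 CPM (3.57-fold, edgeR adjusted p = 3.8e-09), and SAT1, which acetylates polyamines, rose 2.38-fold. The largest rises were in histone genes of the chromosome 6 cluster, H2BC9 (4.04-fold), H2BC8 (3.93-fold) and H2BC7 (3.80-fold), and in an unnamed gene among them at 26195595 to 26199293 (ENSG00000282988, 3.97-fold). FOS, an immediate early transcription factor, rose 2.91-fold.

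By edgeR's quasi-likelihood test 970 of 15517 genes changed under JQ1-FCPF with sgRNA against without, 319 higher and 651 lower, and 239 of them by over 2-fold. Groups did not overlap for 22.6% of all genes, where chance gives 10%. Without JQ1-FCPF without sgRNA replicate 2 the count was 487, and without its replicate 3 it was 428. With only these 2 groups in the fit it was 351, and without the 2 libraries that stand apart it was 1600.

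Of 32 tested replication-dependent and variant histone genes, 19 were higher and 0 lower under JQ1-FCPF with sgRNA than without (20 higher adjusted over the list alone). Among them were H2BC21, H2AC11 and H3C10 at 3.11-, 2.62- and 2.49-fold. HIST1H3B, a histone gene not among the tested members of the list, rose 3.05-fold. The median log2 change of the 32 was 0.65 (camera adjusted p = 6.83e-16), and adjusted p = 0.474 with an estimated correlation. BET response markers rose in 5 of 10 cases and fell in 0 (6 higher adjusted over the list alone), through TXNIP, H2BC21, H2BC5 (2.08-fold), ZCCHC24 (1.47-fold) and H2BC12 (1.47-fold), of which 3 are histone genes also on the histone list. Their camera adjusted p was 1.05e-05, and adjusted p = 0.0552 with an estimated correlation. HEXIM1, a marker which BET inhibitors are known to raise, had a log2 fold change of 0.01 (95% interval -0.29 to 0.32). Its log2 CPM was 7.39 and 7.12 in replicates 1 and 3 with sgRNA and 6.44 in replicate 2, against 6.97 to 7.06 without sgRNA. NF-kB targets fell in 9 of 18 cases and rose in 0 (10 lower adjusted over the list alone; camera adjusted p = 2.5e-07), and adjusted p = 0.0169 with an estimated correlation. They included the inhibitors NFKBIA (2.48-fold) and TNFAIP3 (2.35-fold) and the chemokines CXCL2 (12.3-fold) and CXCL3 (10.9-fold), which were low throughout, CXCL2 at 4.80 ± 1.09 against 0.382 ± 0.0837 CPM.

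Members of the erythroid and myeloid lists were called lower with sgRNA under JQ1-FCPF. Of 31 erythroid genes 6 fell and 0 rose (7 lower adjusted over the list alone), with LMO2, NFE2 and KLF1 at 1.68-, 2.20- and 1.69-fold (camera adjusted p = 0.0221), and adjusted p = 0.526 with an estimated correlation. GATA2, a haematopoietic transcription factor, fell 1.43-fold, and 3 of 11 myeloid and megakaryocytic genes fell and 0 rose (4 lower adjusted over the list alone; camera adjusted p = 0.0325), and adjusted p = 0.575 with an estimated correlation. Of 56 MYC target genes 6 fell and 0 rose (9 lower adjusted over the list alone), with PPAN and PPRC1 at 1.95- and 1.53-fold (camera adjusted p = 0.000232), and adjusted p = 0.715 with an estimated correlation. E2F2 fell 2.04-fold and E2F8 1.80-fold, the only 2 of 37 S phase and E2F genes called (2 adjusted over the list alone; camera adjusted p = 0.148). IRF1 fell 2.13-fold among 19 interferon genes, of which 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.945).

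Among stress and lipid genes under JQ1-FCPF, 8 of 31 ATF4 and unfolded protein genes rose with sgRNA and 1 fell (12 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.000161), and adjusted p = 0.526 with an estimated correlation. HERPUD1 rose 1.66-fold and ASNS, asparagine synthetase, 1.64-fold. HSPA5, the main chaperone of the endoplasmic reticulum, rose 1.48-fold, and its edgeR adjusted p of 0.00843 became 0.0541 without JQ1-FCPF without sgRNA replicate 2 and 0.0617 with only these 2 groups in the fit, in a range from 0.000163 to 0.0617 over 13 alternatives. Of 25 cholesterol genes 3 rose and 0 fell (5 higher adjusted over the list alone; camera adjusted p = 4.02e-05), and adjusted p = 0.488 with an estimated correlation, with INSIG1 at 1.80-fold and IDI1 at 1.56-fold. Immediate early genes moved both ways, 5 of 28 higher and 5 lower (6 and 8 adjusted over the list alone; camera adjusted p = 0.561), with KLF2 2.39-fold higher and FOSL1 2.10-fold lower. G2/M genes had a median log2 change of 0.13 with 0 of 35 higher and 1 lower (0 and 1 adjusted over the list alone; camera adjusted p = 0.00812), and adjusted p = 0.744 with an estimated correlation.

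Other lists did not pass camera's test in this comparison. Members called higher and lower were 2 and 0 of 24 heat shock genes (camera adjusted p = 0.0747), 1 and 3 of 23 p53 target genes (0.955), 1 and 1 of 26 NRF2 genes (0.168), 3 and 1 of 28 glycolysis genes (0.0747), 0 and 2 of 12 genes of the MYC dimerisation network (0.213), 0 and 1 of 21 genes of BET proteins and P-TEFb (0.365) and 0 of 25 Mediator and chromatin cofactors (0.739). None of 69 ribosomal protein genes (0.195) and 13 mitochondrially encoded genes (0.789) was called. Markers of other cell types gave 1 call, among 5 fibroblast markers (0.109), and 0 among 5 epithelial (0.365), 2 B cell and 3 T and NK cell markers, of which the last 2 lists were too short for the test. Adjusted over the list alone, the calls of these lists were 2 and 0, 1 and 3, 1 and 1, 4 and 2, 2 and 2, 0 and 1, and 0 in the order of the first sentence, and 2 among the fibroblast markers. The median and mean log2 change differed in sign for interferon genes (0.14 and -0.08), p53 target genes (0.04 and -0.01) and Mediator and chromatin cofactors (-0.02 and 0.02). Mitochondrially encoded genes had a median of -0.05 and a mean of -0.01 where the direction by camera was up, and immediate early genes had a median of -0.06 and a mean of 0.

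**Figure D3:**
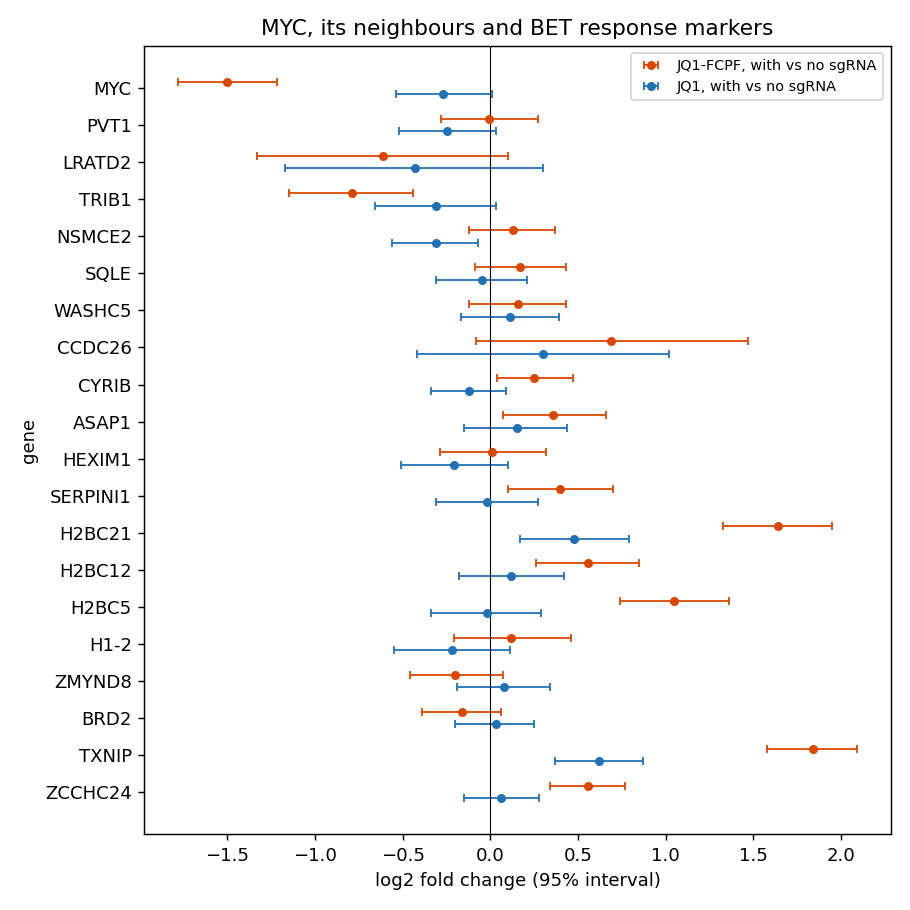
Log2 fold change with its 95% interval for MYC, its neighbours on chromosome 8 and BET response markers, with against without sgRNA, under JQ1-FCPF and under JQ1 (n = 3 per group). MYC lies at -1.50 under JQ1-FCPF and at -0.27 under JQ1, and TXNIP at 1.84 and 0.62.

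The same sgRNA was compared under unconjugated JQ1. HES1 fell from 65.8 ± 7.41 to 36.8 ± 6.38 CPM (1.79-fold, log2 fold change -0.84 ± 0.12, edgeR adjusted p = 0.00855) and BHLHE40 fell from 148 ± 4.36 to 95.6 ± 2.52 CPM (1.55-fold, edgeR adjusted p = 0.00623). The groups did not overlap for either gene, which the rule for naming required. Over all genes they did not overlap for 15.4%, where chance gives 10%. No other gene was called, with 1264 at an unadjusted p under 0.05 and 6 called by DESeq2. TXNIP had a log2 fold change of 0.62 (95% interval 0.37 to 0.87, edgeR adjusted p = 0.146), and it was called by DESeq2, without JQ1 with sgRNA replicate 2, and without the 2 libraries that stand apart. The count was 0 without JQ1 without sgRNA replicate 1, 1 without its replicate 2, 1 without its replicate 3 and 1 without JQ1 with sgRNA replicate 1. HES1 had an adjusted p of 0.0816, 0.122 and 0.0515 without replicates 1 and 3 without sgRNA and replicate 1 with sgRNA, and BHLHE40 had 0.0519 and 0.0578 without replicates 1 and 2 without sgRNA. Over 13 alternatives these values ranged from 3.77e-08 to 0.174 for HES1 and from 7.12e-10 to 0.0998 for BHLHE40. The count was 0 with only these 2 groups in the fit, 80 with no filter on low counts, 4 after the correction for GC content and length and 9 without the 2 libraries that stand apart.

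For JQ1 with against without sgRNA, lists passed camera's test with the preset correlation while 0 of their members were called, and none passed with an estimated correlation. Besides those that follow they were myeloid and megakaryocytic genes, NF-kB targets, cholesterol genes and G2/M genes, with 2, 2, 0 and 0 members lower adjusted over the list alone, camera adjusted p = 0.00658, 0.0229, 0.0297 and 0.00262, and adjusted p = 0.526, 0.285, 0.626 and 0.676 with an estimated correlation. The 13 mitochondrially encoded genes had a median log2 change of 0.73 with 0 called (10 higher adjusted over the list alone; camera adjusted p = 3.28e-07), and adjusted p = 0.561 with an estimated correlation. Ribosomal protein genes had a median of -0.20 with 0 of 69 called (0 adjusted over the list alone; camera adjusted p = 5.47e-13), and adjusted p = 0.63 with an estimated correlation. Beside these lists, the mitochondrial share of counts was 7.46% in JQ1 with sgRNA replicate 1 against 3.06% and 2.79% in replicates 2 and 3. The share of ribosomal protein genes was 8.11% in that replicate against 11.22% and 10.53% in replicates 2 and 3, and 10.97% to 11.7% in JQ1 without sgRNA. Immediate early genes had a median of -0.20 with 0 of 28 called (3 lower adjusted over the list alone; camera adjusted p = 0.000232), and adjusted p = 0.526 with an estimated correlation.

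The difference between the 2 sgRNA effects was tested directly as the interaction of compound and sgRNA. MYC, HES1, FOXA2, LPAR5, CITED2 and CYP26A1 had a lower ratio of with to without sgRNA under JQ1-FCPF than under JQ1, by 3.47-fold for FOXA2 and 2.61-fold for HES1 (edgeR adjusted p = 0.00305 and 0.0012). ZNF689, a zinc finger gene, had a difference of 3.06-fold and E2F2 of 2.18-fold (edgeR adjusted p = 0.00124 and 0.00187). TXNIP and the histone genes H2AC11, H2BC21 and HIST1H3B had a higher ratio, by 2.32-, 2.35-, 2.23- and 4.84-fold. HIST1H3B had a log2 fold change of 1.61 with sgRNA under JQ1-FCPF and of -0.66 under JQ1, where it was not called (edgeR adjusted p = 0.569). NF-kB targets were lower in 4 of 18 cases, CXCL2 and NFKBIA among them (6 adjusted over the list alone; camera adjusted p = 0.000129), and adjusted p = 0.0432 with an estimated correlation. Both named genes were already lower with JQ1 without sgRNA than in the control (edgeR adjusted p = 0.00208 and 0.00349). BET response markers were higher in 3 of 10 cases (4 adjusted over the list alone; camera adjusted p = 4.1e-05), and adjusted p = 0.0741 with an estimated correlation. Histone genes were higher in 9 of 32 cases (21 adjusted over the list alone; camera adjusted p = 4.84e-20), and adjusted p = 0.321 with an estimated correlation. MYC target genes had a median of -0.13 with 1 of 56 lower (1 adjusted over the list alone; camera adjusted p = 0.00815), and adjusted p = 0.783 with an estimated correlation. G2/M, ATF4, heat shock, cholesterol and NRF2 genes had medians of 0.21, 0.18, 0.17, 0.16 and 0.21 with 0, 1, 0, 1 and 0 members higher (1, 8, 1, 1 and 0 adjusted over the list alone, and 1 of the ATF4 genes lower). Their camera adjusted p was 2.9e-05, 0.0002, 0.00437, 0.0174 and 0.0297, and adjusted p = 0.621, 0.526, 0.626, 0.621 and 0.704 with an estimated correlation. Ribosomal protein and mitochondrially encoded genes had medians of 0.25 and -0.74 with 0 called (0 adjusted over each list alone; camera adjusted p = 2.24e-08 and 0.00782), and adjusted p = 0.73 and 0.766 with an estimated correlation, beside the shares of counts of 8.11% and 7.46% in JQ1 with sgRNA replicate 1.

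In all 122 genes had such a difference by edgeR, 30 higher and 92 lower, and 267 did by DESeq2. The count fell to 68, 50 and 61 without replicates 1, 2 and 3 of JQ1 without sgRNA, to 62 and 58 without replicates 2 and 3 of JQ1-FCPF without sgRNA, and to 74 without JQ1-FCPF with sgRNA replicate 1. It rose to 346 without JQ1-FCPF with sgRNA replicate 2. With only the 4 treated groups in the fit it was 81, with no filter on low counts 316 and without the 2 libraries that stand apart 511.

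For JQ1-FCPF without sgRNA against the control few genes passed the test. SKIL, an inhibitor of SMAD signalling, fell from 33.8 ± 0.278 CPM in the control (1.99-fold, log2 fold change -0.99 ± 0.12, edgeR adjusted p = 0.000785), with all 3 treated libraries below all 3 controls, as the rule for naming required. It was the 1 gene called, with 285 at an unadjusted p under 0.05, and DESeq2 called 3, SKIL, SMAD7 and BHLHE40. SKIL kept its call without each of the 6 libraries in turn. The count was 2 with only these 2 groups in the fit, 2 after the correction for GC content and length, and 4 without the 2 libraries that stand apart. The groups did not overlap for 7.5% of genes, where chance gives 10%. TXNIP and HEXIM1 had log2 fold changes of 0.04 (95% interval -0.21 to 0.29) and 0.03 (-0.27 to 0.33). Histone genes had a median log2 change of 0.19 with 0 of 32 called (1 higher adjusted over the list alone; camera adjusted p = 8.58e-07), and adjusted p = 0.618 with an estimated correlation. Cholesterol genes had a median of -0.10 with 0 of 25 called (0 adjusted over the list alone; camera adjusted p = 0.000129), and adjusted p = 0.516 with an estimated correlation. S phase and E2F, myeloid and megakaryocytic, heat shock, ATF4, NRF2, MYC target and glycolysis genes also passed with the preset correlation, with 0 members called over all genes or over the list alone. Their medians were -0.06, 0.18, -0.07, -0.06, -0.06, -0.03 and -0.06, with camera adjusted p = 0.00197, 0.00467, 0.00809, 0.0138, 0.0229, 0.0235 and 0.0419, and adjusted p = 0.64, 0.526, 0.64, 0.64, 0.672, 0.797 and 0.704 with an estimated correlation.

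JQ1-FCPF with sgRNA was also set against the control. The genes with the largest falls were FOXA2 (5.32-fold), HES1 (5.22-fold), BHLHE40 (3.93-fold), CYP26A1 (3.76-fold), LPAR5 (3.41-fold), MYC (3.31-fold) and CITED2 (3.25-fold), with edgeR adjusted p between 8.66e-12 for BHLHE40 and 3.52e-06 for CITED2. The largest rises were in H2BC7 (4.91-fold), H2BC8 (4.49-fold), the unnamed histone cluster gene ENSG00000282988 (4.41-fold), H2BC9 (3.97-fold), TXNIP (3.67-fold), HIST1H3B (3.50-fold) and H2BC21 (3.37-fold). FOS was 2.60-fold higher, at 63.4 ± 27.7 against 24.5 ± 1.87 CPM. Histone genes rose in 22 of 32 cases (24 adjusted over the list alone; camera adjusted p = 2.36e-24), and adjusted p = 0.249 with an estimated correlation. BET response markers rose in 5 of 10 cases (5 adjusted over the list alone; camera adjusted p = 4.07e-07), and adjusted p = 0.0328 with an estimated correlation, with H2BC5 2.28-fold and ZCCHC24 1.73-fold higher. NF-kB targets fell in 8 of 18 cases (9 lower and 2 higher adjusted over the list alone; camera adjusted p = 5.63e-07), and adjusted p = 0.0169 with an estimated correlation, with NFKBIA 2.69-fold lower.

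Against that control, MYC target genes fell in 9 of 56 cases (13 adjusted over the list alone; camera adjusted p = 9.82e-07), and adjusted p = 0.621 with an estimated correlation, with PPAN 1.88-fold and PPRC1 1.62-fold lower. Erythroid genes fell in 6 of 31 cases (7 adjusted over the list alone; camera adjusted p = 0.00699), and adjusted p = 0.526 with an estimated correlation, with NFE2 2.13-fold, KLF1 1.85-fold and LMO2 1.71-fold lower. IRF1, an interferon regulatory factor, was 2.73-fold lower, E2F2 2.17-fold and E2F8 1.75-fold lower, and INSIG1 and HERPUD1 were 1.59-fold and 1.40-fold higher. ATF4 genes were higher in 7 of 31 cases and lower in 2 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0101), and adjusted p = 0.635 with an estimated correlation. Cholesterol genes were higher in 3 of 25 cases (3 adjusted over the list alone; camera adjusted p = 0.0285), and adjusted p = 0.626 with an estimated correlation. S phase and E2F genes were lower in 4 of 37 cases (5 adjusted over the list alone; camera adjusted p = 0.00246), and adjusted p = 0.64 with an estimated correlation. G2/M and ribosomal protein genes had medians of 0.11 and 0.08 with 1 of 35 lower and 0 of 69 called (1 and 0 adjusted over the list alone; camera adjusted p = 0.0247 and 0.0193), and adjusted p = 0.772 and 0.864 with an estimated correlation. The comparison called 1119 genes by edgeR, 375 higher and 744 lower, and groups did not overlap for 25.1% of genes, where chance gives 10%. The count was 702, 701 and 542 without control replicates 1, 2 and 3, 543 with only these 2 groups in the fit and 1745 without the 2 libraries that stand apart.

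JQ1 without sgRNA differed from the control in a wide set of genes. MUC4, a membrane mucin, rose from 3.92 ± 0.744 to 15.6 ± 2.42 CPM (3.94-fold, edgeR adjusted p = 0.000332), and ASS1, argininosuccinate synthase, from 13.9 ± 1.80 to 51.2 ± 4.05 CPM (3.70-fold, edgeR adjusted p = 0.000789). TAFA2, AIF1L and ZC3H6 rose 2.73-, 2.63- and 2.53-fold. CPZ rose 2.86-fold (edgeR adjusted p = 0.0134), and lost its call without control replicate 3 (0.0779) and without JQ1 replicate 2 (0.0557). PRR22 and NEFH, a neurofilament gene, fell 2.84- and 2.69-fold, and the immediate early genes EGR1 and FOS fell 2.51- and 2.50-fold. The known BET response markers TXNIP, H2BC21 and HEXIM1 had log2 fold changes of -0.03, 0.09 and -0.38, with 95% intervals of -0.28 to 0.22, -0.22 to 0.41 and -0.69 to -0.08, and none passed (edgeR adjusted p = 0.897, 0.738 and 0.0906). Of the 10 markers 1 rose and 1 fell, ZCCHC24 and BRD2 (1 and 1 adjusted over the list alone; camera adjusted p = 0.632). ZCCHC24 lost its call without control replicates 2 and 3 and JQ1 replicate 2, and BRD2 without control replicates 1 and 3 and each JQ1 replicate, with adjusted p up to 0.0564 and 0.124 over 13 alternatives.

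Some members of the MYC target and S phase lists were called lower with JQ1 without sgRNA than in the control. MYC target genes fell in 17 of 56 cases (28 lower and 1 higher adjusted over the list alone), with UTP20, NOP56 and TFB2M at 1.67-, 1.65- and 1.49-fold (camera adjusted p = 2.36e-10), and adjusted p = 0.526 with an estimated correlation. S phase and E2F genes fell in 11 of 37 cases (13 adjusted over the list alone), with GINS3 and E2F1 at 1.62- and 1.48-fold (camera adjusted p = 5.63e-07), and adjusted p = 0.526 with an estimated correlation. Immediate early genes fell in 6 of 28 cases (7 adjusted over the list alone; camera adjusted p = 0.0002), and adjusted p = 0.526 with an estimated correlation. Of 18 NF-kB targets 5 fell and 1 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.12), with CXCL2, TNFAIP3 and NFKBIA at 3.27-, 1.96- and 1.59-fold lower. DDIT3 and ASNS, of the ATF4 response, rose 1.69- and 1.81-fold, among 4 of 31 members higher and 2 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.159). ITGA2B, a megakaryocyte integrin, rose 2.02-fold, and 2 of 11 myeloid and megakaryocytic genes were higher and 0 lower (5 higher adjusted over the list alone; camera adjusted p = 0.0423), and adjusted p = 0.613 with an estimated correlation. Genes of BET proteins and P-TEFb fell in 4 of 21 cases (8 adjusted over the list alone), Mediator and chromatin cofactors fell in 4 of 25 (7 lower and 1 higher) and histone genes rose in 1 of 32 (1 higher). Their camera adjusted p was 0.0128, 0.0139 and 0.0323, and adjusted p = 0.526, 0.621 and 0.797 with an estimated correlation.

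Mitochondrially encoded genes were lower with JQ1 without sgRNA in 3 of 13 cases (10 adjusted over the list alone; camera adjusted p = 0.00016), and adjusted p = 0.63 with an estimated correlation, and they took 2.62 ± 0.52% of counts against 4.30 ± 1.47% in the control (SD, n = 3). The share was 5.98% in control replicate 1 and 3.24% and 3.67% in replicates 2 and 3. MT-ND1 and MT-CYB, 2 of the 3 called, lost their calls without control replicates 1 and 3, without each replicate of JQ1 without sgRNA, and by DESeq2. Over 13 alternatives the adjusted p of MT-ND1 ranged from 1.76e-17 to 0.131 and that of MT-CYB from 3.06e-16 to 0.15, the highest being without control replicate 1. Ribosomal protein genes had a median log2 change of 0.21 with 0 of 69 called (0 adjusted over the list alone; camera adjusted p = 4.03e-06), and adjusted p = 0.772 with an estimated correlation. In all 1908 genes changed by edgeR, 942 higher and 966 lower, and groups did not overlap for 41% of genes, where chance gives 10%. The count was 950 and 430 without control replicates 1 and 3, and 857, 701 and 696 without replicates 1, 2 and 3 of JQ1 without sgRNA. It was 4521 with only these 2 groups in the fit and 4234 without the 2 libraries that stand apart.

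JQ1 with sgRNA was compared with the control in the same way. ASS1 and MUC4 each rose 2.83-fold, CPZ, a carboxypeptidase gene, 3.23-fold, TAFA2 2.98-fold and ZC3H6 2.60-fold, and GSDMB, a gasdermin gene, 2.83-fold (edgeR adjusted p between 0.000905 for TAFA2 and 0.00609 for GSDMB). NEFH fell 3.17-fold, the immediate early genes FOS, JUN and EGR1 2.82-, 2.77- and 2.50-fold, and RHOB, a small GTPase, 2.73-fold. BAMBI and SMAD7, both inhibitors of TGF-beta signalling, fell 2.42- and 2.21-fold (edgeR adjusted p = 2.82e-05 and 0.000318), and CYP26A1 fell 2.42-fold. TXNIP rose 1.51-fold and ZCCHC24 1.42-fold, and HEXIM1 fell by 0.59 on the log2 scale (edgeR adjusted p = 0.0122, and 0.0512 without control replicate 3, in a range from 1.74e-05 to 0.0512 over 13 alternatives). Of the 10 BET response markers 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.181). H2BC21 lost its call without control replicates 2 and 3 and JQ1 with sgRNA replicate 1, and BRD2 without control replicates 1 and 3 and JQ1 with sgRNA replicates 2 and 3, with adjusted p up to 0.0902 and 0.124 over 13 alternatives.

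Immediate early genes were lower with JQ1 and sgRNA than in the control in 15 of 28 cases (19 adjusted over the list alone; camera adjusted p = 1.07e-08), and adjusted p = 0.325 with an estimated correlation. MYC target genes were lower in 23 of 56 cases (31 adjusted over the list alone; camera adjusted p = 1.53e-11), and adjusted p = 0.526 with an estimated correlation, with MPHOSPH10 and PPRC1 at 1.51- and 1.49-fold. S phase and E2F genes were lower in 9 of 37 cases (18 adjusted over the list alone; camera adjusted p = 1.12e-06), and adjusted p = 0.526 with an estimated correlation, with CCNE2 and GINS3 at 2.14- and 1.76-fold. NF-kB targets fell in 7 of 18 cases and rose in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00398), and adjusted p = 0.124 with an estimated correlation, with CXCL3, TNFAIP3 and NFKBIA at 3.36-, 1.96- and 1.74-fold lower. Heat shock genes, Mediator and chromatin cofactors, and genes of BET proteins and P-TEFb fell in 5 of 24, 7 of 25 and 6 of 21 cases and rose in 0 (8, 7 and 7 lower adjusted over the list alone). Their camera adjusted p was 0.00353, 0.00815 and 0.0288, and adjusted p = 0.622, 0.613 and 0.526 with an estimated correlation. POLR2A, the largest subunit of RNA polymerase II, fell 1.54-fold, ITGA2B rose 2.21-fold and MVD, of cholesterol synthesis, 1.41-fold. By edgeR 2211 genes changed, 1119 higher and 1092 lower, and groups did not overlap for 34.5% of genes, where chance gives 10%. The count was 1431, 1141 and 726 without control replicates 1, 2 and 3, and 3582 without the 2 libraries that stand apart.

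The 4 comparisons with the control share its 3 libraries. SKIL was the 1 gene called in the same direction in all 4, with log2 fold changes of -1.06, -1.03, -0.99 and -1.01 (SE 0.12 each) for JQ1 without and with sgRNA and JQ1-FCPF without and with sgRNA. Simulated unchanged groups against the same controls gave 0 such genes in each of 20 draws. These draws were centred on the mean of those controls, so they cannot show what a chance deviation of the controls would give. Independent lists of these sizes would share 0.00021 genes lower and 0 higher. JQ1-FCPF without sgRNA called 1 gene lower and 0 higher, so the shared count could not exceed 1. The 3 controls are too few to split, and part of the overlap may come from sharing them. DESeq2 gave 3 such genes, SKIL, SMAD7 and BHLHE40.

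The 2 related compounds were compared at the same dose and time. Without sgRNA, JQ1-FCPF gave EGR1 2.59-fold higher and PRR22 3.11-fold higher than JQ1 (edgeR adjusted p = 0.00407 and 0.00491), and CXCL2 and TNFAIP3 3.87- and 1.97-fold higher. Of the 18 NF-kB targets, to which these last 2 belong, 5 were higher and 2 lower (5 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.064, and adjusted p = 0.484 with an estimated correlation). ASS1, MUC4 and AIF1L were 3.09-, 2.80- and 2.36-fold lower, and ASNS was 1.81-fold lower (edgeR adjusted p between 0.00331 for AIF1L and 0.00533 for ASNS). CPZ was also lower, and FOS and NEFH were higher (edgeR adjusted p = 0.0233, 0.0165 and 0.0109). They lost their calls in 6, 5 and 2 of 13 alternatives, with edgeR adjusted p up to 0.0991, 0.0883 and 0.0605. MYC was not called, with a log2 difference of 0.14 (95% interval -0.14 to 0.41, edgeR adjusted p = 0.554), nor was TXNIP, with 0.07 (-0.18 to 0.32). MYC target genes were higher with JQ1-FCPF in 13 of 56 cases (19 adjusted over the list alone; camera adjusted p = 2.24e-08), and adjusted p = 0.613 with an estimated correlation. S phase and E2F genes were higher in 7 of 37 cases (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000129), and adjusted p = 0.621 with an estimated correlation. Mitochondrially encoded genes were higher in 3 of 13 cases (11 adjusted over the list alone; camera adjusted p = 1.22e-05), and adjusted p = 0.621 with an estimated correlation, with 4.57 ± 1.56% of counts against 2.62 ± 0.52%. MT-ND1 and MT-CYB lost their calls without each replicate of JQ1 without sgRNA, without replicates 2 and 3 of JQ1-FCPF without sgRNA, and by DESeq2, with adjusted p over 13 alternatives up to 0.137 and 0.135. Immediate early genes, genes of BET proteins and P-TEFb, and Mediator and chromatin cofactors were higher in 4 of 28, 4 of 21 and 1 of 25 cases (6, 8 and 1 adjusted over the list alone; camera adjusted p = 0.00197, 0.00713 and 0.0363), and adjusted p = 0.618, 0.516 and 0.63 with an estimated correlation. G2/M, cholesterol and ATF4 genes were lower in 4 of 35, 5 of 25 and 7 of 31 cases and higher in 0, 0 and 1 (8, 8 and 8 lower and 1, 1 and 1 higher adjusted over the list alone). Their camera adjusted p was 0.000161, 0.000584 and 0.0051, and adjusted p = 0.621, 0.526 and 0.621 with an estimated correlation. Ribosomal protein genes had a median of -0.16 with 0 of 69 called (0 adjusted over the list alone; camera adjusted p = 0.000113), and adjusted p = 0.797 with an estimated correlation. By edgeR 1210 genes differed, 638 higher and 572 lower, and groups did not overlap for 36.2% of genes, where chance gives 10%. The count was 280, 76 and 370 without replicates 1, 2 and 3 of JQ1 without sgRNA and 302 and 136 without replicates 2 and 3 of JQ1-FCPF without sgRNA. It was 2959 with only these 2 groups in the fit and 3554 without the 2 libraries that stand apart.

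With sgRNA, JQ1-FCPF gave lower MYC than JQ1 by 2.14-fold (edgeR adjusted p = 8.14e-05) and lower HES1 by 2.48-fold (edgeR adjusted p = 9.64e-06). FOS was 7.32-fold higher, TXNIP 2.43-fold higher, and the histone genes HIST1H3B and H2BC7 3.54- and 3.14-fold higher. These 6 genes passed in all alternatives run. EGR1 and JUN were 3.66- and 2.49-fold higher, H2BC21 and H2BC5 2.27- and 2.02-fold higher, POLR2A 1.65-fold higher, FOXA2, RHOH, NFE2 and E2F2 3.07-, 2.44-, 2.04- and 1.86-fold lower, and these passed except with only the 2 groups in the fit, where their adjusted p was 0.0696 to 0.125. BCL3 was also lower (edgeR adjusted p = 0.00852), and lost its call in 3 of 13 alternatives, with edgeR adjusted p up to 0.229. SERPINI1, a BET response marker, had a log2 difference of 0.00 (95% interval -0.29 to 0.29). MYC target genes had a median log2 difference of 0.13, opposite in sign to that of MYC, and camera's direction was up, with 0 of 56 called higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.00583), and adjusted p = 0.775 with an estimated correlation.

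Histone genes were higher with JQ1-FCPF and sgRNA than with JQ1 and sgRNA in 19 of 32 cases (26 adjusted over the list alone; camera adjusted p = 1.28e-28), and adjusted p = 0.173 with an estimated correlation. Immediate early genes were higher in 10 of 28 cases (12 higher and 2 lower adjusted over the list alone; camera adjusted p = 3.53e-06), and adjusted p = 0.516 with an estimated correlation. BET response markers were higher in 4 of 10 cases (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.5e-07), and adjusted p = 0.0328 with an estimated correlation. HEXIM1, 1 of the 4, lost its call without JQ1 with sgRNA replicates 2 and 3, without JQ1-FCPF with sgRNA replicates 1 and 3, and with only these 2 groups in the fit, with adjusted p up to 0.287 over 13 alternatives. NF-kB targets were lower in 3 of 18 cases and the MYC dimerisation network in 1 of 12, MYC itself (7 and 1 adjusted over the list alone; camera adjusted p = 0.00398 and 0.00809), and adjusted p = 0.124 and 0.285 with an estimated correlation. Mediator and chromatin cofactors were higher in 3 of 25 cases (3 adjusted over the list alone; camera adjusted p = 0.00144), and adjusted p = 0.526 with an estimated correlation. S phase and E2F genes had a median of 0.12 with 1 of 37 lower, E2F2 (2 higher and 1 lower adjusted over the list alone), and ribosomal protein genes of 0.07 with 0 of 69 called (0 adjusted over the list alone). Their camera adjusted p was 0.0164 and 0.0095, with the direction up, and adjusted p = 0.755 and 0.85 with an estimated correlation. Beside these lists, FOS and EGR1 in JQ1-FCPF with sgRNA replicate 2 were at log2 CPM of 5.00 and 7.72, against 6.39 and 9.13 in replicate 1 and 6.23 and 9.06 in replicate 3. By edgeR 458 genes differed, 183 higher and 275 lower, and groups did not overlap for 15.5% of genes, where chance gives 10%. The count was 217 and 261 without JQ1 with sgRNA replicates 2 and 3, 68 and 108 without JQ1-FCPF with sgRNA replicates 1 and 3, and 2757 without replicate 2 of that group. It was 11 with only these 2 groups in the fit, 822 with no filter on low counts and 3176 without the 2 libraries that stand apart.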

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

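Of the tests below, the comparison of library deviations, the MYC level of the library that stands apart, the count without it, the correlation of the sgRNA effects and the correlation with replicate 2 included were chosen only after the results were seen, as were the rule that a correlation's interval must lie wholly beyond its bound, the division of the interaction splits by what they keep, and the correction for GC content and length as an alternative.

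The effect of the sgRNA differed between JQ1-FCPF and JQ1 by a test of the difference itself, the interaction, for 122 genes by edgeR's quasi-likelihood test. Among named genes the difference on the log2 scale was -1.24 for MYC, -1.80 for FOXA2, -1.61 for ZNF689, -1.44 for LPAR5, -1.43 for CITED2, -1.38 for HES1 and -1.26 for CYP26A1. For NF-kB targets it was -3.47 for CXCL2, -1.18 for NFKBIA and -1.23 for TNFAIP3, and for transcription factors -1.12 for E2F2, -0.98 for NFE2 and -0.64 for LMO2. It was 2.27 for HIST1H3B, 1.76 for H2BC7, 1.71 for FOS, 1.23 for H2AC11, 1.22 for TXNIP and 1.16 for H2BC21. Benjamini-Hochberg adjusted p-values by edgeR ranged from 0.0012 for HES1 and LPAR5 to 0.0325 for FOS. CXCL2, TNFAIP3 and NFKBIA were already lower with JQ1 without sgRNA than in the control (edgeR adjusted p = 0.00208, 0.00178 and 0.00349). Their starting levels under JQ1 thus left less room for a fall with sgRNA, and CXCL2 was low throughout. With sgRNA, NFKBIA differed between the compounds at edgeR adjusted p = 0.0155, and lost that call in 4 of 13 alternatives. FOS, NFE2 and LMO2 lost their calls in 11, 10 and 8 of 19 alternatives, with adjusted p up to 0.0938, 0.0907 and 0.0981, H2BC7 without JQ1 without sgRNA replicate 1 (adjusted p = 0.0524) and TNFAIP3 without replicate 2 of that group (0.0553), in ranges from 1.55e-09 to 0.0524 and from 0.00425 to 0.0553. Of 100 splits of the 12 treated libraries, the real one included, 9 gave as many genes, the highest of the others 312. All 8 others as large kept the real split under JQ1-FCPF and so carry the response to the sgRNA there, and the remaining 91 gave at most 2 genes, so these splits do not say whether chance gave the count of 122. MYC, HES1 and TXNIP kept this call in all 19 alternatives.

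The JQ1 libraries and JQ1-FCPF with sgRNA replicate 2 lay together on the first principal component, apart from the control. Against GC content or gene length as the whole cause of the difference between JQ1 without sgRNA and the control, 2302 genes were called after the correction, and against a mislabelled JQ1 library, MYC in that replicate was at log2 CPM 5.84, below the 6.69 to 7.34 of the 6 JQ1 libraries. A state of the cultures or libraries cannot be told apart from the compound, since the labels tie no library to a culture or library round, and the correlation across 15517 genes of that replicate's deviation from replicates 1 and 3 with the JQ1 difference (r = 0.492, 95% interval 0.480 to 0.503) decides nothing, because the replicate was picked for lying with the JQ1 libraries. Whether a BET inhibition program was the whole difference stays undecided. Across the 1908 called genes that difference was correlated with replicates 1 and 3 of JQ1-FCPF with sgRNA minus JQ1-FCPF without sgRNA. The result was r = 0.281 (0.239 to 0.322), under the bound of 0.3 set beforehand but not by its interval, as the rule adopted later requires. With replicate 2 included it was r = 0.641 (0.614 to 0.667), so the value rests on that library. These intervals treat genes as independent and leave out the spread between libraries. The reference also has JQ1-FCPF on both sides, so it measures the sgRNA effect under that compound. Neither a high nor a low r could therefore show or exclude such a program. Beside this, the BET markers TXNIP and HEXIM1 had log2 fold changes of -0.03 and -0.38 in JQ1 without sgRNA against the control, and neither was called.

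The response to the sgRNA under JQ1-FCPF was weighed against 3 explanations. Without the replicate that stands apart 961 genes were called and after the correction for GC content and length 1223, which argues against either as the whole cause of the 970. An effect of the sgRNA that does not need the conjugate could contribute. Across those 970 genes the sgRNA effect under JQ1 correlated with that under JQ1-FCPF at r = 0.471 (95% interval 0.420 to 0.518), with a slope of 0.14. The interval treats genes as independent, and r was not computed without JQ1 with sgRNA replicate 1, which stands apart. Without that library the log2 fold changes of MYC and HES1 under JQ1 were -0.14 and -0.71, against -0.27 and -0.84 with it. The design names recruitment of the compound through the tag as a biological explanation, which was not tested.

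For the comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. Only the real split, 1 of 10, gave as many genes for JQ1 without sgRNA (1908), JQ1 with sgRNA (2211), JQ1-FCPF without sgRNA (1) and JQ1-FCPF with sgRNA (1119) against the control, for JQ1-FCPF with against without sgRNA (970) and for JQ1-FCPF against JQ1 without sgRNA (1210), where the highest other split gave 0, and for JQ1 with against without sgRNA (2), where it gave 1. For JQ1-FCPF against JQ1 with sgRNA (458), 3 of 10 splits gave as many, the highest 1055, from JQ1 replicates 1 and 3 with JQ1-FCPF replicate 2 against the rest, which points to a structure of the samples.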

How the results depend on the processing

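Leaving out JQ1-FCPF with sgRNA replicate 2 and JQ1 with sgRNA replicate 1 together, and the GC and length correction, were chosen only after the results were seen. Over 193 results of named genes other than MYC, each of them called, and their 2617 values under alternatives, 2463 kept their direction and call, 154 lost their call and 0 reversed. These results were chosen as called from the same libraries, most with no overlap between the groups, so reversals could hardly occur. Named genes that were not called are outside this tally, and among them TXNIP gained a call for JQ1 with against without sgRNA by DESeq2. Some called genes are outside it too, such as H2BC12 for JQ1-FCPF with against without sgRNA. Not all results in the tally are given in the text above, such as those of UHRF1 and CDC25C. Of 123 values for MYC under alternatives, 120 kept direction and call and 3 gained a call. In the order JQ1 without sgRNA, JQ1 with sgRNA, JQ1-FCPF without sgRNA and JQ1-FCPF with sgRNA against the control, JQ1-FCPF with against without sgRNA, JQ1 with against without sgRNA, JQ1-FCPF against JQ1 with and without sgRNA, and the interaction, genes called without the 2 libraries numbered 4234, 3582, 4, 1745, 1600, 9, 3176, 3554 and 511. With only the compared groups in the fit they numbered 4521 for JQ1 without sgRNA, 2 for JQ1-FCPF without sgRNA and 543 for JQ1-FCPF with sgRNA against the control, 351 for JQ1-FCPF with against without sgRNA, 0 for JQ1 with against without sgRNA, 11 and 2959 for JQ1-FCPF against JQ1 with and without sgRNA, and 81 for the interaction. With no filter on low counts they numbered 80 for JQ1 with against without sgRNA, 822 for JQ1-FCPF against JQ1 with sgRNA and 316 for the interaction. DESeq2 called 3 for JQ1-FCPF without sgRNA against the control, 6 for JQ1 with against without sgRNA and 267 for the interaction, and 3 genes in all 4 treated groups. The GC and length correction gave 2 for JQ1-FCPF without sgRNA against the control and 4 for JQ1 with against without sgRNA. MYC in JQ1 without sgRNA against the control passed with no filter (-0.38), with only those groups (-0.36) and without the 2 libraries (-0.35). Of 216 list tests 84 passed with the preset and 5 with an estimated correlation. Neither of the 2 libraries is in the comparison of JQ1 without sgRNA with the control, where the main fit called 1908 genes. Its rise to 4234 without them, and to 4521 with only those groups, shows that the main count depends on libraries outside the comparison through the shared fit. Both are in the comparison of JQ1-FCPF with JQ1 with sgRNA, which went from 458 to 11 with only those groups. The cause of the other changes was not tested.

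Leaving out each library in turn, calls ranged in the same order over 430 to 1338, 726 to 1858, 1 to 1, 542 to 1201, 428 to 1129, 0 to 3, 68 to 2757, 76 to 973 and 50 to 346, and genes called in all 4 treated groups over 1 to 1. The log2 fold change of MYC ranged over -0.40 to -0.31, -0.80 to -0.50, -0.35 to -0.09, -1.75 to -1.69, -1.63 to -1.37, -0.44 to -0.14, -1.22 to -0.92, 0.01 to 0.27 and -1.37 to -1.06.

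The title letters gave no sign of pairing the libraries, which does not exclude it. Deviations of 30 same-letter pairs had a mean correlation of -0.019, from -0.238 to 0.311, with 4 over 0.1. For 60 different-letter pairs the mean was 0.01, from -0.339 to 0.237, with 15 over 0.1. Of 15 libraries, 4 correlated best with their own letter. With the letter as a block the counts were 1739, 1998, 1, 1008, 833, 3, 380, 1122 and 93. Depth and spread limit small changes: 50% of simulated 1.5-fold changes were recovered for JQ1 without sgRNA against the control.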

Other observations

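The test of the SMAD list below was chosen only after the fall of SKIL was seen.

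Other lists passed camera's test with the preset correlation only. Against the control, G2/M genes rose with JQ1 without sgRNA in 6 of 35 cases and fell in 1 (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00197), and adjusted p = 0.665 with an estimated correlation. Cholesterol genes rose with JQ1 and sgRNA in 7 of 25 cases and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00584), and adjusted p = 0.575 with an estimated correlation. Heat shock genes were higher with JQ1-FCPF and sgRNA than with JQ1 and sgRNA in 2 of 24 cases, DNAJB1 and HSPA1B (6 adjusted over the list alone; camera adjusted p = 1.22e-05), and adjusted p = 0.526 with an estimated correlation. The libraries of the groups overlapped for both: HSPA1B was at log2 CPM 6.89 in JQ1-FCPF with sgRNA replicate 2, against 8.13 and 8.25 in replicates 1 and 3 and 6.79 to 7.01 with JQ1 and sgRNA. Both lost their calls without JQ1-FCPF with sgRNA replicates 1 and 3 and with only these 2 groups in the fit, and over 13 alternatives the edgeR adjusted p ranged from 1.7e-15 to 0.205 for DNAJB1 and from 3.01e-14 to 0.251 for HSPA1B.

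SKIL, an inhibitor of SMAD signalling and itself a target of it, fell in all 4 treated groups against the control, with edgeR adjusted p = 0.000144 and 8.11e-05 for JQ1 without and with sgRNA and 0.000785 and 1.29e-05 for JQ1-FCPF without and with sgRNA. The hypothesis that SMAD-dependent transcription fell was tested on 14 other target genes of the pathway, leaving out genes seen to fall. In JQ1-FCPF without sgRNA against the control their median log2 change was -0.05. Camera gave an unadjusted p = 0.033, or 0.0573 with an estimated correlation, so the fall passed only under the preset correlation. In this comparison several fixed lists also passed under the preset correlation with 0 members called, so this test does not decide the question. The treated groups share the control libraries. Transfection, Cas9FCPF and compound cannot be told apart as the source of the fall in these comparisons.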
